A study of Homo sapiens with 6 samples.

How the data were processed

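RNA-seq libraries of total RNA were made from Huh7 cells, an established human hepatocellular carcinoma line, 1 week after puromycin selection. According to the labels, 3 libraries came from cells with a scrambled short hairpin RNA and 3 from cells with a hairpin against ABL1, the gene of a non-receptor tyrosine kinase. Each library was assigned to its group and replicate number from its title. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The hairpin sequence, and whether more than 1 hairpin was used, are not given in the sources used here.

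The deposited table holds 10191 rows, each a single RefSeq transcript, and 1 signal value per library, which the authors computed before deposit. Per the submitters' processing notes, HISAT2 2.0.4 and HTSeq 0.6.1 were used with genome build hg38, with no role or order stated. The annotation, the strand setting, the filter on rows and the treatment of reads that lie in several transcripts are not given in the sources used here. From the values, each library's deposited signal is a scaled square root: every squared value equals one step per library times a whole number plus 3/8. Squaring the values, dividing by the step and subtracting 0.375 gave whole reads within a tolerance of 0.05 for 100% of rows in each of the 6 libraries. The recovered totals ran from 6651413 to 10487862 reads per library. Rows of genes with several RefSeq transcripts had fewer reads: the median of the mean count was 198 for genes with 1 RefSeq transcript, 74.0 for those with 2, 59.2 for those with 3 to 4, 38.9 for those with 5 to 7 and 48.2 for those with 8 or more. Only 405 symbols had more than 1 row.

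The normalized count used throughout is the recovered read count multiplied by the library's relative step, which keeps the authors' scale factors. Rows were matched by RefSeq identifier to a RefSeq gene reference (97.8% of rows). By their identifiers, 8554 rows were coding and 1637 non-coding transcripts. Exons, positions and 3′ UTRs were taken from the GENCODE 29 annotation of GRCh38. Another 13 rows whose symbol had become a date were named through their identifier, and 37 rows had no symbol. Transcripts with a mean normalized count of at least 10 over the 6 libraries were tested, which kept 8600 transcripts of 8348 genes and left out 1591 rows. The test was limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3 on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment over all transcripts tested and a threshold of 0.05. A log2 change is the mean of the knockdown minus the mean of the scrambled libraries on that scale, which understates the change of transcripts with few reads. Values are given as mean ± SD with n = 3 per group, and each log2 change has its standard error (SE) where quoted in full. Pooled read ratios of ABL1 have exact 95% intervals, which cover counting error only, since reads copied by PCR are not independent molecules.

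The 31 gene lists were fixed before the data were examined, and 29 had at least 5 tested members. Each gene entered with its most abundant tested transcript. The lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes. Fry asks whether a list's genes move, on balance, in 1 direction, or, in its mixed form, whether they change in either direction, and does not compare them with other genes. The genes named in the text were chosen by a rule fixed before the data were examined: ABL1, ABL2, NOTCH1 and MYC whatever their values; the 12 largest rises and 12 largest falls among transcripts past the threshold with non-overlapping groups, a symbol and a mean at or above the median of those tested; and, per list, up to 4 members past the threshold by smallest p, or the 2 with the smallest p if none passed. Where a list had 5 or fewer rises or falls, those outside the rule are also named, and a few further members and family members are; these were chosen after their values were seen. The values of a few single genes are not reported here.

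The recovery and the fit were tested on simulated data. Of 50 transcripts simulated at each fold change for this comparison, among 8591 transcripts tested, 4% were recovered at 1.25-fold, 48% at 1.5-fold, 80% at 2-fold and 100% at 4-fold, and 8 of 124 calls were false. Of the simulated gene lists, 10 of 10 shifted and 0 of 30 unshifted lists were called by camera. The simulated genes varied independently of each other, so this cannot show how camera performs where genes are correlated. Before averaging, the libraries were compared: chi-square per degree of freedom within a group ran from 5.89 to 10.6, so no pair was a duplicate. Alternatives to pseudocount, filter, scaling, variance model, threshold and set test, a replicate block and the omission of each library were fixed in advance. The design assumed either normalized values or raw counts, and the table held a square-root signal instead. The test for normalized values was therefore applied after inversion of the square root, and the count model listed as an alternative was not run. In its place limma's voom was run on the recovered reads; this, the deposited square-root values as they stand, equal total reads per library and reads summed per gene were chosen after seeing the data. Words of 7 bases in 3′ UTRs of the GENCODE 29 transcripts were searched in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, in coding transcripts with a mean of at least 50 reads and a 3′ UTR of at least 30 bases. Each word held by at least 20 transcripts got a z, the difference of mean log2 change between transcripts with and without it after a fit on length and GC content, divided by its standard error. An exploratory look, whose other results are not reported, also covered words of other lengths and coding sequences. Figures were drawn with matplotlib 3.10.9. No library was left out.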

Results

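RNA was sequenced from Huh7 cells, a human hepatocellular carcinoma line, after selection for a short hairpin RNA. There were 6 libraries, 3 with a scrambled hairpin and 3 with a hairpin against ABL1. The scrambled libraries held 10487862, 7713451 and 9137608 counted reads and the knockdown libraries 7952645, 6651413 and 7483809. Of 10191 transcripts in the table, 8600 had enough reads to be tested. The first principal component took 69.9% of the variance and separated the 2 groups. Correlations of log2 counts across transcripts were 0.984 to 0.988 within a group and 0.940 to 0.951 between groups.

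The comparison asked which transcripts differ in Huh7 cells when ABL1, which encodes a non-receptor tyrosine kinase, is knocked down. The knockdown libraries had less RNA of genes for DNA replication and mitosis, of ribosomal protein genes, of MYC and its targets, and of immediate early genes. These lists passed camera with its preset correlation, and none of them did with an estimated correlation. NOTCH1, a receptor of the Notch pathway, and MYC, a transcription factor that drives cell growth, were 4.05 and 3.89 times lower in the knockdown group. In all, 4460 transcripts changed (51.9% of those tested), of which 2105 rose and 2355 fell.

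ABL1 had 2 tested transcripts, which differ in their first exon and moved in opposite directions. NM_007313, the more abundant one, fell from 72.1 ± 1.09 to 11.1 ± 2.33 normalized counts (SD, n = 3 each). Its log2 change was -2.62 (SE 0.26, limma adjusted p = 4.11e-06). It had 88, 64 and 76 reads in the scrambled libraries and 14, 9 and 9 in the knockdown libraries, so that each knockdown library was below each scrambled one. The pooled ratio of knockdown to scrambled reads was 0.154 (exact 95% interval 0.103 to 0.224). NM_005157 rose from 8.74 ± 1.84 to 20.5 ± 3.75 normalized counts, a log2 change of 1.15 (SE 0.36, adjusted p = 0.0180). Its reads were 11, 6 and 11 in the scrambled and 18, 17 and 24 in the knockdown libraries, with a pooled ratio of 2.31 (1.45 to 3.77). This rise lost its call without scrambled replicate 2 (log2 change 0.99, adjusted p = 0.0508) and without knockdown replicate 3 (1.01, adjusted p = 0.0738), and its adjusted p was 0.00498 to 0.0392 under the alternatives that kept the call on this transcript alone. Summed over both transcripts, ABL1 went from 80.9 ± 2.14 to 31.6 ± 2.34 normalized counts, a pooled ratio of 0.390 (0.304 to 0.498). In GRCh38, ABL1 lies on the plus strand of chromosome 9. NM_007313 runs from 130713946 to 130885683 and NM_005157 from 130835066 to 130887675, with 11 exons each. Exon 1 of each (130713946 to 130714455, and 130835066 to 130835525) is in that transcript alone, exons 2 to 10 are shared, and the last exon is longer in the model of NM_005157. Whether the RefSeq record of NM_007313 ends where its model does was not checked. Reads of the shared exons cannot tell the transcripts apart, and how the authors assigned them is not given in the sources used here. No transcript of ABL2, the paralog, was tested.

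**Figure D1:**
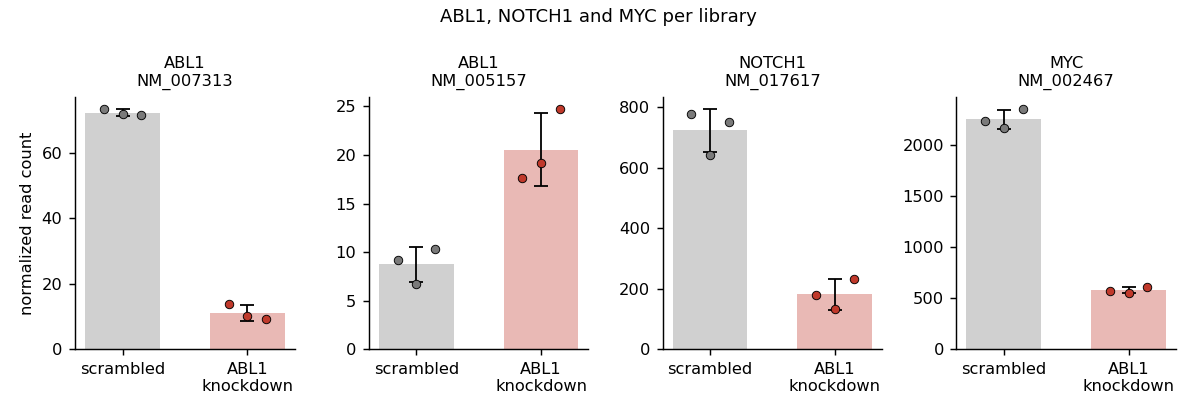
Normalized read counts (y axis, from 0, a separate scale per panel) of both ABL1 transcripts, NOTCH1 and MYC in scrambled (grey) and ABL1 knockdown (red) libraries; bars are means, error bars SD (n = 3) and points single libraries. ABL1 NM_007313, NOTCH1 and MYC are lower in each knockdown library than in each scrambled one, with log2 changes of -2.62, -2.02 and -1.96, and ABL1 NM_005157 is higher, at 1.15.

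**Figure D2:**
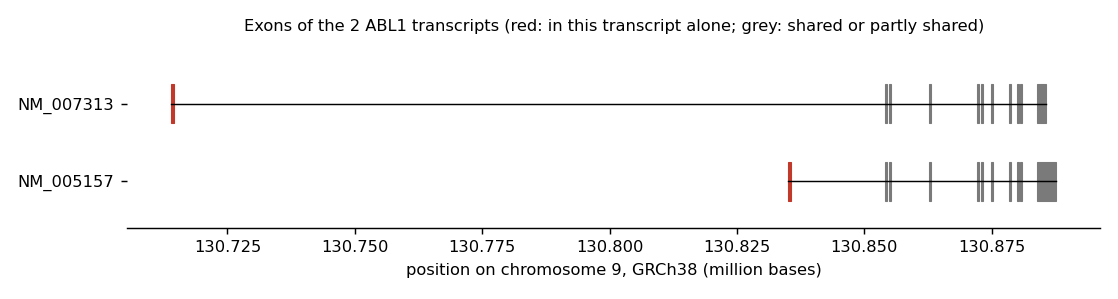
Exons of the 2 ABL1 transcripts (boxes) along chromosome 9 of GRCh38 (x axis, Mb), drawn to scale with introns as lines and the 5′ end at the left. Red boxes mark exon 1 of each, found in that transcript alone, and grey boxes mark exons shared fully or, for exon 11, in part.

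NOTCH1 (NM_017617, chromosome 9, 136494433 to 136545786, minus strand) fell from 724 ± 71.8 to 182 ± 50.5 normalized counts (log2 change -2.02, SE 0.17, adjusted p = 9.13e-07). MYC (NM_002467, chromosome 8, 127736069 to 127741434, plus strand) fell from 2247 ± 97.1 to 577 ± 28.7 (log2 change -1.96, SE 0.08, adjusted p = 3.05e-09). Of 17 tested Notch pathway genes, 7 fell and 6 rose, and the list as a whole did not pass (adjusted p = 0.560). The ligand JAG1 fell by 1.22 on the log2 scale, the receptor NOTCH3 by 1.48 and DTX1, an E3 ligase, by 2.46. The Notch targets HES1 (-0.49) and NRARP (-1.10) also fell, while HEY2 (1.47), another target, rose. The median log2 change of the 17 genes was -0.02, and 0.15 when libraries were scaled to equal totals.

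Growth and division genes went down together. The list of MYC targets includes MYC itself. None of its 27 tested genes rose and 19 fell, among them the exosome component EXOSC5 (-1.87), the nucleolar methyltransferase FBL (-0.88) and HK2 (-1.01), with a camera adjusted p = 0.000241. That became adjusted p = 0.257 with an estimated correlation. Among 21 genes of the G1/S phase and DNA replication 14 fell and 0 rose (adjusted p = 0.00122, and adjusted p = 0.257 with an estimated correlation). They included the helicase subunit MCM6 (-1.38), DSCC1 (-2.32), the transcription factor E2F1 (-1.13) and TYMS (-0.90). Of 24 genes of G2/M and mitosis 21 fell, 22 adjusted over the list alone with RANGAP1 (-0.86, transcript NM_001278651), and 0 rose (adjusted p = 7.98e-09, and adjusted p = 0.260 with an estimated correlation). TUBB4B (-1.60), TOP2A (-1.51), CDC20 (-1.19), PLK1 (-1.08) and the proliferation marker MKI67 (-2.93) were among them. Of 59 cytosolic ribosomal protein genes 44 fell and 0 rose (adjusted p = 2.35e-09, and adjusted p = 0.348 with an estimated correlation), led by RPS19 (-1.46) and RPS2 (-0.95). The replication-dependent histones, whose family members share sequence, had 8 of 15 members lower and 0 higher (adjusted p = 0.0181, and adjusted p = 0.260 with an estimated correlation), such as HIST1H1C (-1.43) and HIST1H2AC (-0.92).

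Hepatocyte genes were divided. Among 36 genes of secreted plasma proteins 20 fell, or 21 adjusted over the list alone with ITIH2 (-0.19), and 5 rose (adjusted p = 0.00448, and adjusted p = 0.348 with an estimated correlation). Retinol carrier RBP4 fell by 1.16 on the log2 scale, the acute phase proteins ORM1 and ORM2 by 2.33 and 2.74, APOA2 by 0.97 and ALB by 0.42. Those that rose included PLG (0.60), FGG (0.68, transcript NM_021870), SERPIND1 (0.42) and AGT (0.22). With reads summed per gene the rise of FGG lost its call (log2 change 0.51, limma adjusted p = 0.0804). The counts became 17 falls and 9 rises with quantile normalization and 16 falls and 9 rises with equal totals. With quantile normalization this list did not pass (adjusted p = 0.0916, within a range of 0.00298 to 0.348 over all alternatives of camera). Of 25 genes of hepatocyte metabolism and transport 6 rose, such as CYP1A1 (1.74), which oxidises aromatic compounds, and MAT1A (0.85), and 6 fell, such as the iron regulator HAMP (-1.11) and CYP27A1 (-0.56), and the list did not pass (adjusted p = 0.610). Of 12 liver transcription factors CEBPD (-1.57), NR0B2 (-1.35), FOXA3 (-0.79), GATA6 (-0.52) and FOXA1 (-0.48) fell, and PPARGC1A (1.01) and ONECUT2 (0.39) rose (list adjusted p = 0.560). Of 13 fetal liver and liver tumour markers KRT19 (-0.83), LIN28B (-0.60) and SOX9 (-0.48) fell, and DLK1 (1.16) rose with overlapping groups (list adjusted p = 0.341). The median of these markers was -0.10, and 0.08 with equal totals.

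Energy metabolism was lower in part. Of 13 glycolysis genes 8 fell, including PGK1 (-1.50), ALDOC (-1.07), ENO2 (-1.47) and GAPDH (-1.05), and 0 rose (adjusted p = 0.0136, and adjusted p = 0.348 with an estimated correlation). Of 16 hypoxia response genes 9 fell, such as DDIT4 (-1.12) and BNIP3 (-0.80), and CITED2 (0.97) rose (list adjusted p = 0.0882, 0.0362 with no filter on low counts, and 0.0362 to 0.348 over all alternatives of camera). Of 27 nuclear genes of oxidative phosphorylation 15 fell, such as ATP5F1B (-0.88), COX7B (-1.07) and CYC1 (-0.61) (adjusted p = 0.00452, and adjusted p = 0.348 with an estimated correlation). COX5A (0.23) and NDUFA6 (2.76, adjusted p = 0.0188) rose. The groups overlapped for NDUFA6, with normalized counts of 45.9, 47.1 and 37.5 in the scrambled and 796, 931 and 35.1 in the knockdown libraries, so that its call rested on single libraries: it was lost without scrambled replicate 3 (adjusted p = 0.0604), knockdown replicate 1 (0.0664) or knockdown replicate 2 (0.0829) and with voom (0.115), and without knockdown replicate 3 the log2 change was 4.28 (adjusted p = 2.59e-09). No transcript of the 15 mitochondrially encoded genes was among those tested, and they were not analysed here. Among 14 genes of cholesterol synthesis and uptake 7 fell, such as EBP (-0.82) and SQLE (-0.27), and 2 rose, among them HSD17B7 (0.34), or 3 adjusted over the list alone with ACAT2 (0.68, transcript NM_001303253) (list adjusted p = 0.549). The balance of this list depended on the scaling: 2 rose and 3 fell with quantile normalization, and 4 rose and 3 fell with equal totals. Of 11 genes of fatty acid synthesis PNPLA3 (-1.57) and FASN (-0.34) fell, and ME1 (0.48), ELOVL5 (1.43, transcript NM_001242831) and ACACB (0.31) rose (list adjusted p = 0.5998). In that list 6 rose and 1 fell with quantile normalization, where FASN had a log2 change of -0.02 (adjusted p = 0.877), and 5 rose and 1 fell with equal totals. Of 10 genes of fatty acid oxidation and PPAR targets the acylcarnitine carrier SLC25A20 (1.38), ACADL (3.13) and the near-identical pair ACOT1 (1.09) and ACOT2 (1.04) rose. FABP1 (-0.91), CPT2 (-0.88), PDK4 (-2.08) and CPT1A (-1.41) fell, 5 adjusted over the list alone with HADHA (-0.17), and the list did not pass (adjusted p = 0.926).

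Among stress and signalling lists, the immediate early genes fell. Of 18 such genes 13 fell, including CCND1 (-1.65), EGR1 (-1.63), FOS (-2.52) and IER2 (-0.76), and 0 rose (adjusted p = 0.000241, and adjusted p = 0.348 with an estimated correlation). Of 18 unfolded protein response genes 6 fell, such as SDF2L1 (-0.92) and PDIA4 (-0.66), and EDEM1 (0.67), the sensor kinase EIF2AK3 (0.91), DNAJB9 (0.33), DNAJC3 (0.29) and ATF6 (0.26) rose (list adjusted p = 0.588). Of 16 genes of the ATF4 and amino acid response DDIT4, GDF15 (-1.33), STC2 (-0.81), SLC7A5 (-0.94) and SLC7A1 (-0.32) fell, and SESN2 (0.87), SLC7A11 (0.43), PSPH (0.28) and MARS (0.23) rose (list adjusted p = 0.560). Of 13 p53 targets GDF15, AEN (-0.81), TNFRSF10A (-0.93) and PPM1D (-0.48) fell, and SESN2 and BTG2 (0.39) rose (list adjusted p = 0.588). Among 18 interferon response genes 7 rose, among them IFIT2 (2.10) and the RNA sensor IFIH1 (1.43), or 9 adjusted over the list alone with MX2 (0.19) and DDX58 (0.35), and IFITM2 (-1.98), USP18 (-0.72), HERC5 (-0.77) and IRF1 (-0.41) fell (list adjusted p = 0.322). With equal totals 11 interferon response genes rose and 3 fell. Of 9 NF-kB and inflammatory genes RELB (-0.83), IER3 (-2.23), ICAM1 (-0.27) and NFKBIA (-0.23) fell and 0 rose (list adjusted p = 0.185). With quantile normalization or equal totals 2 of them fell, since ICAM1 (-0.17 and -0.10) and NFKBIA (-0.12 and -0.06) lost their calls.

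Matrix and signalling targets were mixed. Of 22 genes of epithelial-mesenchymal transition and matrix 9 fell, such as the protease inhibitor TIMP2 (-1.58) and LOXL2 (-1.65), and 7 rose, such as the intermediate filament gene VIM (1.11) (list adjusted p = 0.875). Of 11 YAP/TAZ targets CTGF (-2.80), GADD45B (-1.57), ANKRD1 (-0.52), ARHGEF17 (-0.42) and TEAD1 (-0.31) fell, and PTPN14 (0.97) and CRIM1 (0.51) rose (list adjusted p = 0.299). Of 16 WNT/beta-catenin targets 9 fell, among them CCND1, MYC and the secreted WNT antagonists NOTUM and DKK1 (-1.85), and BAMBI (0.35) and APCDD1 (0.62) rose (adjusted p = 0.0374, and adjusted p = 0.610 with an estimated correlation). This list did not pass without scrambled replicate 1 (adjusted p = 0.0795), scrambled replicate 3 (0.0515) or knockdown replicate 1 (0.0579), and over all alternatives of camera its adjusted p was 0.0126 to 0.610. Of 18 ABL substrates and actin regulators 8 fell, such as RIN1 (-1.48), CRKL (-0.76) and CBL (-0.94), and WASL (0.49) and WASF2 (0.65) rose (list adjusted p = 0.225). That became 4 rises and 5 falls with quantile normalization and 5 of each with equal totals.

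Markers of other cell types were measured as well. Of 8 biliary markers 6 fell, among them CLDN4 (-1.86), KRT19, TFF3 (-1.44) and ANXA4 (-0.52), or 7 adjusted over the list alone with EPCAM (-0.22), and CFTR (1.92) rose (list adjusted p = 0.0172, and adjusted p = 0.260 with an estimated correlation). Of 6 fibroblast and stellate markers PDGFRA (1.84), LUM (2.11), COL3A1 (1.54) and COL1A2 (0.62) rose, from 335 ± 17.6, 23.7 ± 8.71, 31.3 ± 7.73 and 7820 ± 522 normalized counts in the scrambled libraries, and COL1A1 (-1.03) fell (list adjusted p = 0.0939). Of 5 endothelial markers CDH5 (-1.14), PECAM1 (-0.59) and STAB2 (-1.03) fell and VWF (1.08) rose (list adjusted p = 0.560). The 3 tested immune markers were too few for a list test, with LAPTM5 (-2.39) and FCER1G (-0.79) lower and LYZ (0.21) higher.

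Among called transcripts with non-overlapping groups and a mean at or above the tested median, the largest rise was the long non-coding RNA UCA1. It went from 205 ± 61.1 to 1937 ± 36.2 normalized counts (log2 change 3.28, adjusted p = 1.69e-08). It was followed by the glucuronosyltransferase UGT2B11 (3.01), DCDC1 (3.00), the metallothionein MT1X (2.78), B3GNT9 (2.45), the coagulation factor subunit F13B (2.39), PBLD (2.38), MAP1A (2.34), MT2A (2.21), MLLT11 (2.19), the estrogen sulfotransferase SULT1E1 (2.16) and TMEM144 (1.96). Under the same conditions the largest fall was EPB41L4B, from 501 ± 26.9 to 56.3 ± 2.14 (log2 change -3.13, adjusted p = 3.05e-09). After it came SORCS2 (-2.83), CTGF (-2.80), CLIC4 (-2.77), ORM2 (-2.74), FOXQ1 (-2.60), RNF157 (-2.53), S100P (-2.34), ORM1 (-2.33), the kinase EEF2K (-2.33), CNOT11 (-2.26) and PCNP (-2.24). ORM1 and ORM2, the metallothioneins and UGT2B11 have near-identical relatives, as ribosomal protein genes have pseudogenes, so their values are uncertain where reads were shared.

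**Figure D3:**
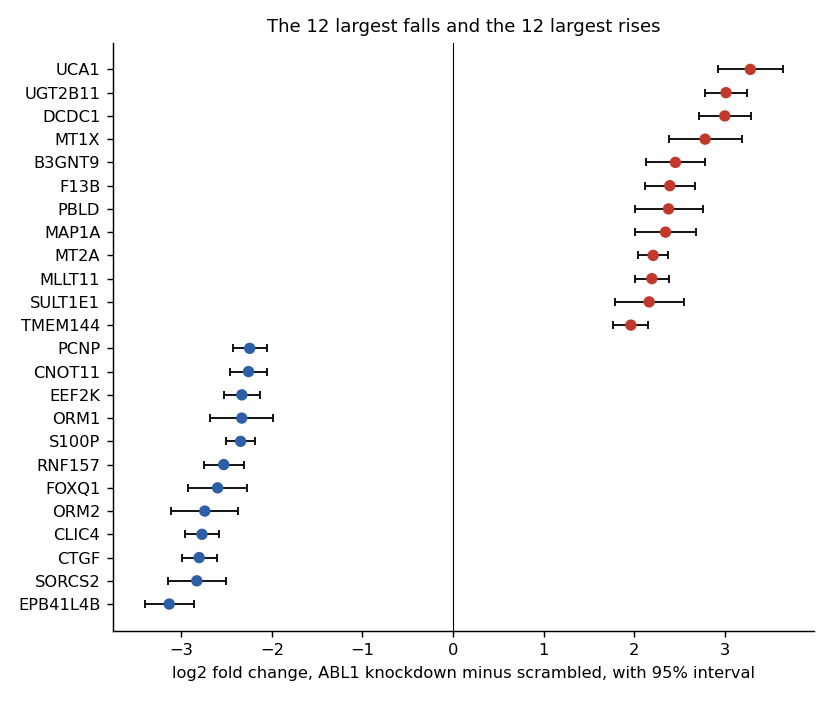
Log2 fold changes, ABL1 knockdown minus scrambled (x axis), of the 12 largest rises (red) and 12 largest falls (blue) chosen by the fixed rule; points are estimates from 3 libraries per group and bars their 95% intervals. They run from -3.13 for EPB41L4B to 3.28 for UCA1.

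In limma's test 681 transcripts rose and 776 fell by at least 2-fold, and 103 rose and 136 fell by at least 4-fold. The groups did not overlap for 58.9% of transcripts, against 10% by chance. The median log2 change of all tested was 0.0018, with an interquartile range from -0.44 to 0.43. Rises made up 47.2% of the changes with the authors' scale factors and 63.6% with equal totals (2967 rose, 1699 fell), which raised the median by 0.17. The normalized totals were 8.65 ± 0.0857 M reads (SD, n = 3, M for mega) in the scrambled and 7.67 ± 0.137 M reads in the knockdown libraries.

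By camera with the preset correlation 11 of 29 lists passed, all of them lower in the knockdown, and their medians stayed below 0 under quantile, median-of-ratios and equal-total scaling. With an estimated correlation 0 lists held, while fry called 23 in 1 direction and 29 in either. Adjusted over the list alone, the counts of rises and falls differed from those over all genes only in the 6 lists where both are given. The median, mean and test differed in sign for the liver transcription factors (median 0.14, mean -0.17, test lower), matrix genes (median 0.03, mean -0.11, test lower) and fatty acid oxidation (median -0.07, mean 0.12, test higher), and for fatty acid synthesis (median 0.15) fry pointed lower. With equal totals the medians of fatty acid oxidation (0.11), the unfolded protein response (from -0.07 to 0.11), the ATF4 response (from -0.10 to 0.08), p53 targets (from -0.04 to 0.14) and ABL substrates (from -0.14 to 0.03) turned positive. With quantile normalization that of the matrix genes turned to -0.05, and those of fatty acid oxidation, the unfolded protein response and the ATF4 response turned positive. Falls outnumbered rises among matrix genes and in the unfolded protein and ATF4 responses, but with equal totals 9 matrix genes rose and 6 fell, 6 unfolded protein response genes rose and 5 fell, and 6 ATF4 response genes rose and 4 fell. With quantile normalization 8 unfolded protein response genes rose and 6 fell, and 7 ATF4 response genes rose and 4 fell. Equal totals also gave 1 rise and 13 falls among MYC targets, 2 and 12 among G1/S genes, 1 and 20 among G2/M genes, 1 and 39 among ribosomal proteins, 1 and 11 among immediate early genes, 2 and 6 in glycolysis, 4 and 7 in hypoxia, 4 and 11 in oxidative phosphorylation, 4 and 5 among liver transcription factors and 2 and 3 among YAP/TAZ targets.

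**Figure D4:**
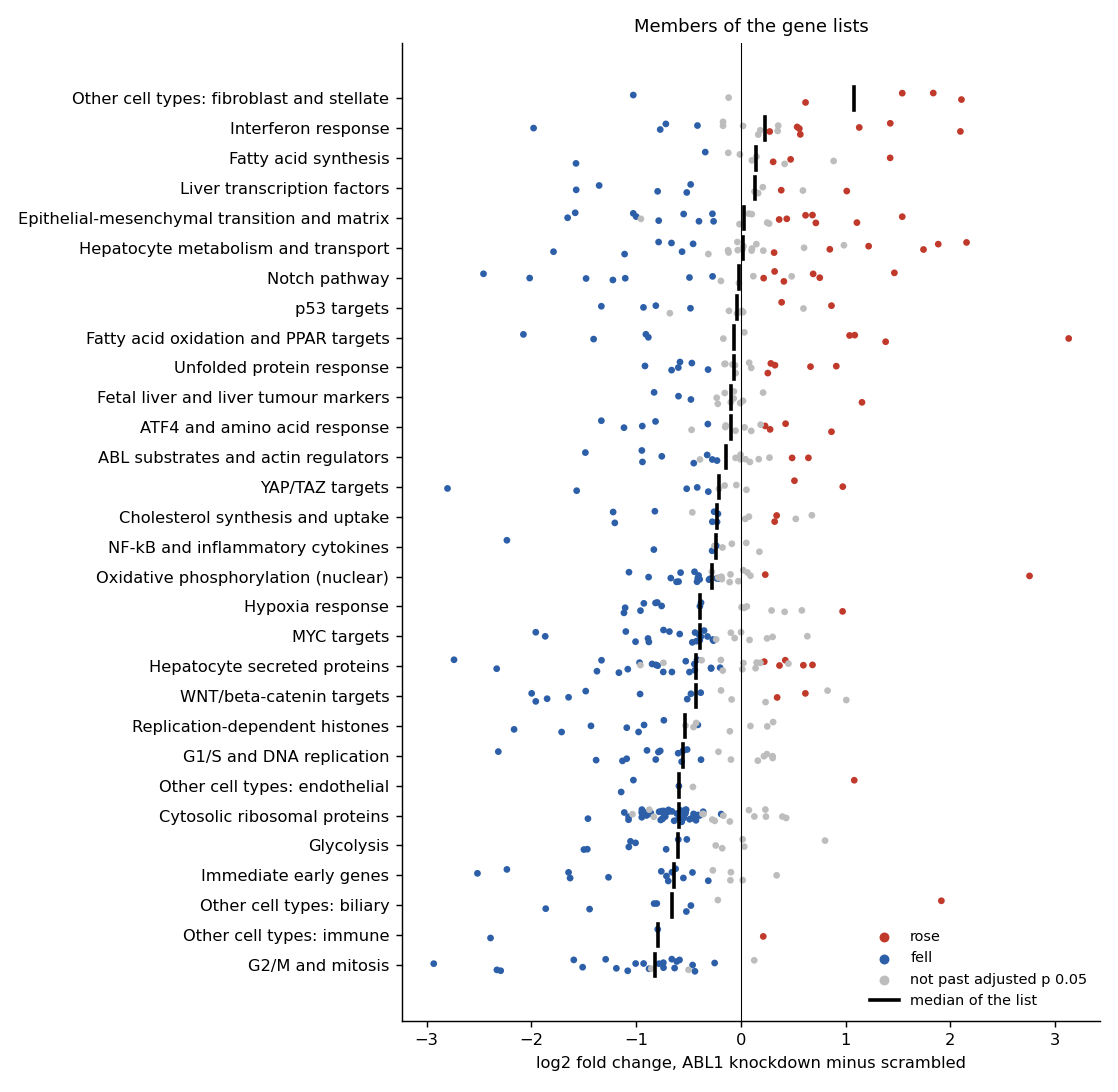
Log2 fold change, ABL1 knockdown minus scrambled (x axis), of each tested member of the fixed gene lists (y axis, ordered by median, with a small vertical spread for legibility); red points rose, blue fell, grey did not pass adjusted p 0.05, and black bars are list medians. The medians run from -0.82 for G2/M and mitosis to 1.08 for fibroblast and stellate markers, and those of the Notch, fetal liver, fatty acid oxidation, unfolded protein response, ATF4, p53 and ABL substrate lists turn from negative to positive with equal totals, while that of the matrix genes turns negative with quantile normalization.

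Each group had only 3 libraries, and besides ABL1 NM_005157, given above, 22 calls among the named genes ended when 1 library was left out, with adjusted p values of 0.0507 to 0.181 where they did. These were ACACB, AGT, ANKRD1, APCDD1, ATF6, CITED2, COX5A, DLK1, DNAJC3, FASN, FCER1G, FGG, HSD17B7, ICAM1, IRF1, LYZ, MARS, MRPL3, NDUFA6, NFKBIA, STAB2 and WASF2. Among named genes that were called, and besides NDUFA6, the log2 change moved by more than 1.5 times for FGG (0.43) and ATF6 (0.16) without scrambled replicate 1 and for FASN (-0.22) without knockdown replicate 2. With quantile normalization the calls of ALB, FASN, ICAM1, NFKBIA, SLC7A1 and SQLE ended, and with equal totals those of ANKRD1, FASN, FCER1G, ICAM1, IRF1, NFKBIA, PPM1D, SLC7A1, SQLE, STAB2 and TEAD1. No named gene other than ABL1 NM_005157, when summed with NM_007313, changed direction under an alternative while it was called.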

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

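Voom on the recovered reads, the deposited square-root values, equal total reads, reads summed per gene and the recomputation of the genes named outside the rule were chosen after seeing the data; the other alternatives were fixed before the data were examined, of which a count model on the recovered reads was not run. The number of changed transcripts was 4460 with the settings of the report, 3997 to 4821 under the other planned settings that tested a similar number of transcripts, 4464 with voom, 4482 with the square-root values, 4666 with equal totals, 4406 of 8406 genes with summed reads and 3931 to 4142 when 1 library was left out. With a 2-fold change also required it was 1457 (681 rose and 776 fell), which follows from the stricter rule. With a mean of at least 100 reads, 3163 of 5159 tested transcripts changed (61.3%), of which 1361 rose and 1802 fell (43.0% rises); fewer were tested, and the cause of the lower share of rises was not tested. The replicate number as a block gave 4821 changes, but no pairing by number was seen: correlations between same-numbered libraries after removal of the group means were 0.0471, 0.0765 and 0.0768, and for no number was the same-numbered library the best partner.

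ABL1 NM_007313 kept its fall under every alternative that tested it (with a mean of at least 100 reads neither ABL1 transcript was), from -2.77 to -2.51 when 1 library was left out. The rise of ABL1 NM_005157 ran from 0.99 to 1.27 when 1 library was left out, and it lost its call without scrambled replicate 2 (adjusted p = 0.0508) and without knockdown replicate 3 (0.0738). With reads summed per gene the change was -1.33 (adjusted p = 0.000116), which reverses that of NM_005157 by construction, since the sum went from 256 to 91 reads, of which NM_007313 had 228 and 32.

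With an estimated correlation in camera the adjusted p was 0.257 for MYC targets and for G1/S, 0.260 for G2/M, histones and biliary markers, 0.348 for secreted proteins, glycolysis, oxidative phosphorylation, immediate early genes and ribosomal proteins, and 0.610 for WNT targets. With fry, which does not compare a list with other genes, 12 further lists passed: Notch 0.0123, liver transcription factors 0.0216, fetal liver 0.0214, hypoxia 0.00152, cholesterol 0.00563, unfolded protein response 0.00594, ATF4 0.0260, NF-kB 0.00271, YAP/TAZ 0.00647, ABL substrates 0.00382, endothelial 0.0395 and fibroblast markers 0.000536. Hypoxia passed with no filter on low counts (0.0362), and secreted proteins did not with quantile normalization (0.0916); the cause was not tested. WNT targets ran from 0.0126 to 0.0795 when 1 library was left out, and did not pass without scrambled replicate 1, scrambled replicate 3 (0.0515) or knockdown replicate 1 (0.0579). Of 133 transcripts named by the rule other than ABL1, 125 kept call and direction under every alternative and 8 did not, and of 71 named beyond it 45 kept them and 26 did not, with 0 reversed in either group. In simulated data at this depth 48% of 1.5-fold changes were recovered. Only 124 of 8591 simulated transcripts were called, against 4460 of 8600 here, so an adjusted p of 0.05 was harder to reach there. Small changes may have been missed here, but the simulation does not give their share.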

Other observations

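The tests of families, of the 2 ABL1 transcripts, of 7-base words by composition and in separate parts of the transcripts, and of scaling were chosen after the results were seen; those of flanking bases, of other splits and of depth were written before. Among 102 gene families, defined by a shared symbol stem and at least 8 tested members, 8 passed camera with the preset correlation, 5 higher and 3 lower, and 0 passed with an estimated correlation, while fry gave adjusted p values of 0.000552 to 0.00364 for the 8. Of 13 PCDHB genes, clustered protocadherins that act in cell adhesion, 12 rose, such as PCDHB3 (log2 change 1.43) and PCDHB11 (2.59), and PCDHB4 (0.06) did not pass (camera adjusted p = 2.80e-06, 0.574 with an estimated correlation). Of 8 genes with the stem MT, the metal-binding metallothioneins, MT2A (2.21), MT1X (2.78), MT1H (2.66), MT1B (2.94), MT1E (1.24) and MT1L (0.79) rose, while MT1A (-0.20) and MT1M (-1.08) did not pass (family adjusted p = 0.0217, 0.847 with an estimated correlation). MT1M passed as a fall with quantile normalization (adjusted p = 0.0475), median-of-ratios scaling (0.0437), a replicate block (0.00133), array weights (0.0304), voom (0.0428), without scrambled replicate 3 (0.0203) and without knockdown replicate 2 (log2 change -1.63, adjusted p = 0.00220). Both families have near-identical members, so single values are uncertain where reads were shared. Of 32 MRPL genes, which encode mitochondrial ribosomal proteins, 18 fell, such as MRPL16 (-1.67) and MRPL18 (-1.44), and MRPL1 (0.54), MRPL15 (0.39) and MRPL3 (0.22) rose (adjusted p = 0.0217, 0.698 with an estimated correlation). Of 15 CEP genes, centrosomal proteins, 11 rose, such as CEP290 (1.18), and CEP192 (-0.61) and CEP250 (-0.70) fell (adjusted p = 0.0475, 0.698 with an estimated correlation). Of 163 long non-coding RNAs with the stem LINC 62 rose and 12 fell (adjusted p = 0.000877, 0.698 with an estimated correlation), and of 13 ABHD genes 8 rose and 0 fell (adjusted p = 0.0217, 0.698 with an estimated correlation). The other 2 stems, RPL and RPS, are mostly the ribosomal proteins of the report. The median of each of these families kept its sign with equal totals and with quantile normalization.

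The ABL1 transcripts moved in opposite directions. Counting error alone is argued against by the exact 95% interval of the pooled ratio of NM_005157, whose lower bound was 1.45, and exchanged libraries are argued against by NM_007313, whose lowest scrambled count was 5.21 times its highest knockdown count. Opposed transcripts were not usual: 7 of 217 genes with several tested transcripts had a rise and a fall (among them ABL1, BCCIP, BORCS8, EXD3, LAMP2 and WDR33), against a median of 16 and a lowest of 7 in 1000 random assignments. Random assignment breaks the link between transcripts of 1 gene, so the comparison with it cannot show how the assignment of reads acts. The assignment of reads from shared exons by the authors, a different use of the first exons and a hairpin that acts on 1 of the transcripts alone may each have a part, and none was tested, because the assignment and the hairpin sequence are not given in the sources used here. A response of the cells to lower ABL1 also stays open.

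Transcripts with the word AAGCATT in the 3′ UTR fell relative to the others: among 16236 words it had the lowest z, -13.0, in 5446 3′ UTRs. Before the fit on length and GC content, the median log2 change was -0.24 in 950 transcripts with the word and -0.03 in those without. Its z values were -13.2, -12.8 and -12.1 in the single knockdown libraries, each set against the same scrambled libraries. They were 2.33, -2.18 and 0.14 in each scrambled library against the others. Length and base composition do not account for this fall, since the lowest of 419 other words of the same bases, AGCATTA, which overlaps AAGCATT, reached -8.03. Nor does chance among many words, since AAGCATT was the lowest word in each of 2 random parts of the transcripts and had a z of at most -8.29 in the other. Among words of any bases the next lowest were AGCATTT (z of -10.7, 1273 transcripts) and GCATTTC (-8.84, 816 transcripts), which also overlap AAGCATT. A candidate explanation is pairing with a small RNA, such as the introduced hairpin, but copies in AU-rich flanks did not pass for a larger fall (difference of medians -0.0568, 95% interval -0.17 to 0.05, permutation p = 0.263, 686 transcripts), which leaves it open. As a description of the pattern and not a test of its source, 7 of the 12 largest falls (EPB41L4B, CTGF, CLIC4, FOXQ1, EEF2K, CNOT11 and PCNP) and 1 of 11 searched largest rises (SULT1E1) hold the word. Other genes chosen by the rule that fell and hold it are FOS, CBL, CRKL, ERO1A, LIN28B, DKK1, DSCC1, TUBB4B, HK2, TIMP2, SOX9, STC2 and USP18. CRIM1, DLK1, EDEM1 and PTPN14, which rose, hold it too. Most searched falls chosen by the rule lack it, among them NOTCH1, MYC, NOTCH3 and JAG1. ABL1 NM_005157, which rose, holds it in exon 11 (chromosome 9, 130886754 to 130886760), within AAGCATTTC. That position is beyond the end of the GENCODE model of NM_007313, and whether the RefSeq record ends there was not checked. An endogenous microRNA and an effect of lower ABL1 were not tested, and the hairpin sequence is not given in the sources used here.

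The number of changed transcripts was large, 4460 of 8600. The 6 libraries allow 10 splits, too few for a share under 0.05; in limma the real split gave 4460 and the highest other 0 (4935 and 172 at an unadjusted p under 0.05), and 1 of the 10 splits, the real one, gave as many. Lower depth of the knockdown libraries is argued against by 4335 changes after thinning to the smallest library, of which 4231 changed the same way in both, and scaling is argued against as the source of the number by at least 4424 changes under 3 other scalings. Scaling could account for the split into rises and falls, since the share of rises went from 47.2% to 63.6% with equal totals. The knockdown and unintended targets of the hairpin both stay open as sources of the changes themselves, and the labels give no batch that could be tested. Any other difference between the groups of cells would coincide with the hairpin and could not be told apart from its effects.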
